A study of Mus musculus with 2 samples.

How the data were processed

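Live CD45+ cells of mouse cochleae were profiled by droplet single-cell RNA sequencing. Per the labels' protocols, cochleae of 6 mice per condition were pooled, digested with enzyme, stained with a CD45 antibody and with 1 of 4 hashtag antibodies directed at MHC class I and CD45, and sorted as 1 suspension of living CD45+ cells per condition. Hashtags 1 to 4 marked sham, day 3, day 7 and day 14 after noise, per the labels' protocols. The labels name the control both as sham treated and as untreated, and give 2 different kit versions, which the values do not settle. Here the control is called sham.

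The 2 deposited matrices hold UMI counts per gene and barcode, as whole numbers, per the file headers written by Cell Ranger 3.1.0. The genome build was mm10, per the submitters' processing notes. How barcodes were chosen as cells is not given in the sources used here; each barcode held at least 500 UMIs. The gene counts of both matrices were identical, and 1 of them also holds the counts of the 4 hashtags, so the gene counts were used once. In all, 1556 barcodes held 15753747 gene UMIs over 31053 genes, with a median of 6485.5 UMIs and 1906 genes per barcode, and 543123 hashtag UMIs.

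Barcodes were assigned to conditions with HTODemux of Seurat 5.3.0 (R 4.3.3, Matrix 1.6.5) at a positive quantile of 0.99 on centred log-ratio counts of the 4 hashtags. This gave 330 sham, 514 day 3, 230 day 7 and 178 day 14 singlets, 152 barcodes without a hashtag and 152 with more than 1. Barcodes without a single hashtag entered no condition. In all singlets, before the cell filter, the leading hashtag had medians of 382, 243, 223.5 and 311 UMIs in the 4 pools, and the other hashtags 2 to 3 UMIs together. Barcodes with fewer than 200 genes or more than 10% mitochondrial UMIs were left out, which kept 1377 barcodes and 1182 singlets with 13050036 gene UMIs. The pools then held 3069615, 5844745, 2473589 and 1662087 gene UMIs (sham, day 3, day 7, day 14), and median mitochondrial percentages of 3.98, 2.64, 3.34 and 3.28.

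The 1230 barcodes that passed and were not hashtag doublets were clustered in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9): counts per 10000 on a log scale, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Clusters were named from 24 marker lists. A cluster took the name of the list whose markers had the highest mean log2 ratio to the median cluster (pseudocount 20 CPM, mean at least 1), if at least 3 of them were 2-fold higher and detected in at least 10% of its barcodes. It stayed unnamed if another list had at least 3 members, and more than its own list, among its 10 leading genes counted without the detection minimum, or if it was shallow and held no marker among them. These naming thresholds were set after the clusters had been seen, whereas the marker lists, gene lists, tests and first set of alternatives were fixed before the data were examined. Names end in "-like" because the classes rest on RNA alone.

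Each pool of day 3, 7 and 14 was compared with the sham pool, the only control. Shares of classes are percentages of the singlets of a pool with Clopper-Pearson 95% intervals. Expression was compared in classes with at least 30 cells in both pools, which left mature neutrophil-like and B cell precursor-like cells on all days and B cell-like cells on day 3. UMIs were summed per class and pool, divided by the class total (CPM), and the ratio to sham was given with an exact conditional Poisson 95% interval. Class totals ranged from 216940 to 1104532 UMIs, so that 2771 to 6793 genes reached 20 UMIs in both pools together. A gene without UMIs on one side was set to 3 UMIs there, which makes its ratio a bound, and no ratio was given under an alternative where both pools held 3 UMIs or fewer.

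Gene sets were 27 lists written by hand from gene functions. A list was summarised as the median log2 ratio of members with at least 20 UMIs in both pools together, where at least 3 were measured. Its counting interval came from 2000 Poisson resamplings, and its percentile from 10000 random lists of the same size matched on 10 bins of mean expression. Lists beyond the percentiles 0.5 and 99.5 and lists used across classes or days were reported. Genes named for a comparison are the 5 highest and 5 lowest by the bound of the interval nearest to 1, among genes with at least 30 UMIs and a ratio of at least 1.5 either way. Mitochondrial, ribosomal protein, unnamed model, immunoglobulin and T cell receptor variable segment, Xist and Y-linked genes were left out of that choice. For a list, 2 to 4 members with the bound farthest from 1 are named, and genes that describe classes or sources follow the marker and cytokine lists. Gene coordinates are those of GENCODE vM21 on GRCm38, which held 30934 of the 31053 gene IDs. Figures were drawn with matplotlib 3.10.9.

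Reads shared between paralogs were not examined, so values of single members of the stefin cluster (Stfa2, BC100530), the MHC class I genes and the immunoglobulin constant genes are uncertain. RNA released by other cells was not removed; the neutrophil gene S100a8, for example, stood at 409 CPM in B cell precursor-like cells against 146641 CPM in mature neutrophil-like cells.

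Alternatives covered hashtag calls (quantiles 0.95 and 0.999, or a leading hashtag with at least 80% of hashtag UMIs and 10 UMIs), the cell filter (at least 500 genes, at most 5% mitochondrial UMIs, no filter), doublets called by Scrublet at an expected rate of 0.05 (3 barcodes), Leiden resolutions 0.5 and 2, singlets alone in the clustering, the denominator of shares, normalization (mean over cells, size factors, total without mitochondrial and ribosomal protein genes), thinning of cells to the 25th percentile of UMIs, list members with at least 5 or 50 UMIs and genes with at least 100 UMIs. Thinning left out the cells below that percentile, so it changed the set of cells as well as their depth. Chosen after the data were seen were leaving out the cell with the most UMIs of each gene, weighting the clusters of a class alike, classes with at least 15 cells, and shares without marrow-stage classes.

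The ratios were tested on simulated data with known folds, built at the depth of 2 comparisons. Counts were drawn from the Poisson model that the intervals assume, so their coverage was fixed in advance and checks the calculation only. UMIs that gather in single cells, as in the real pools, were not simulated. The interval held the simulated ratio for 96.3% of 2737 unchanged genes at the depth of day 3 mature neutrophil-like cells and for 96.2% of 5214 at the depth of day 7 B cell precursor-like cells. In both, 10 of the 10 named genes were among those given a fold. Abundant genes given a fold shift the totals, a shift that the simulated ratio includes, so intervals of unchanged genes excluded 1 for 39.6% at the neutrophil depth and 5.91% at the other. A list of 10 unchanged genes had a median log2 ratio of -0.59 at the neutrophil depth (percentile 30.5). The percentile against random lists allows for such a shift, whereas the interval of a gene does not.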

Results

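Live CD45+ cells sorted from mouse cochleae were profiled in 4 conditions: sham, and days 3, 7 and 14 after noise. Each condition is 1 pool of 6 mice, and there are no replicates. Differences between pools therefore carry no p-values, and every interval given is a 95% interval that covers counting error only. All ratios divide by the same sham pool, so a direction seen on several days is not an independent repeat. After demultiplexing and filtering, 310 sham, 492 day 3, 214 day 7 and 166 day 14 cells remained. Median UMIs per cell were 6085, 8051, 7372 and 6941 in the same order, and median genes per cell were 1955.5, 2112.5, 2011.5 and 2032.5. The Y-linked gene Ddx3y stood at 74.6, 79.2, 63.1 and 83.0 counts per 1000000 (CPM) in the 4 pools, while the X-inactivation transcript Xist had 1, 1, 2 and 0 UMIs.

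The CD45+ cells fell into 11 named classes, each set apart by genes of its lineage. Mature neutrophil-like cells held the secreted protein gene Retnlg (34975 CPM) and the granulocyte growth factor receptor Csf3r (825 CPM), and immature neutrophil-like cells held the granule genes Camp (44960 CPM) and Ngp (39623 CPM). B cell precursor-like cells expressed the surrogate light chain genes Vpreb1 (998 CPM) and Igll1 (542 CPM) and the recombinase Rag1 (224 CPM), whereas B cell-like cells expressed Ms4a1, which encodes CD20 (1226 CPM). B cell-like cells also held the plasma cell marker Jchain (12097 CPM), so plasma cells are not told apart in that class. T cell-like cells carried the receptor component Cd3e (532 CPM), but also the natural killer (NK) receptor Ncr1 (440 CPM against 1245 CPM in NK cell-like cells). The complement gene C1qa marked macrophage-like cells (2126 CPM) and the chemokine receptor Ccr2 monocyte-like cells (1129 CPM). The elastase Elane marked myeloid progenitor-like cells (8133 CPM) and the lectin Siglech plasmacytoid dendritic cell-like cells (2418 CPM). Mast cell or basophil-like cells held the protease Mcpt8 (1240 CPM), but also the progenitor genes Mpo (731 CPM) and Cd34 (176 CPM), so progenitors are not told apart in that class. The monocyte-like cluster was led by the lectin Cd209a and also held MHC class II genes and the dendritic cell genes Clec9a (71.6 CPM) and Xcr1 (69.5 CPM), so monocytes and dendritic cells are not told apart in it. A cluster with Cd163l1 and the gamma delta T cell receptor genes Trdc and Tcrg-C1 stayed unnamed and made up 2.58%, 1.42%, 0.935% and 3.01% of the sham, day 3, day 7 and day 14 cells.

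Did the mix of CD45+ cells differ between the pools? Mature neutrophil-like cells were 18.7% of sham cells (14.5 to 23.5) and 31.3% on day 3 (27.2 to 35.6), 31.8% on day 7 (25.6 to 38.5) and 30.7% on day 14 (23.8 to 38.3). Immature neutrophil-like cells were 6.13% in sham (3.73 to 9.41), 16.5% on day 3 (13.3 to 20.0), 5.14% on day 7 and 11.4% on day 14. Mature and immature neutrophil-like cells together held 24.8% of sham cells and 47.8% of day 3 cells, a ratio of 1.92 (1.48 to 2.52). B cell precursor-like cells held 26.8% of sham (21.9 to 32.1) and 14.0% of day 3 (11.1 to 17.4), a ratio of 0.524 (0.375 to 0.730), against 23.4% on day 7 and 28.3% on day 14. B cell-like cells were 15.2% of sham and 8.33%, 7.94% and 7.83% of days 3, 7 and 14, ratios of 0.550 (0.353 to 0.854), 0.524 (0.282 to 0.930) and 0.517 (0.256 to 0.970). Without the neutrophil classes in the denominator, the day 3 ratio of B cell precursor-like cells was 0.754 (0.540 to 1.05), and those of B cell-like cells were 0.791 (0.507 to 1.23), 0.624 (0.336 to 1.11) and 0.671 (0.333 to 1.26) on days 3, 7 and 14, intervals that all include 1. These shares describe cells that passed a CD45 gate, not numbers of cells per cochlea, and the day 3 pool had 8051 median UMIs per cell against 6085 in sham.

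**Figure D1:**
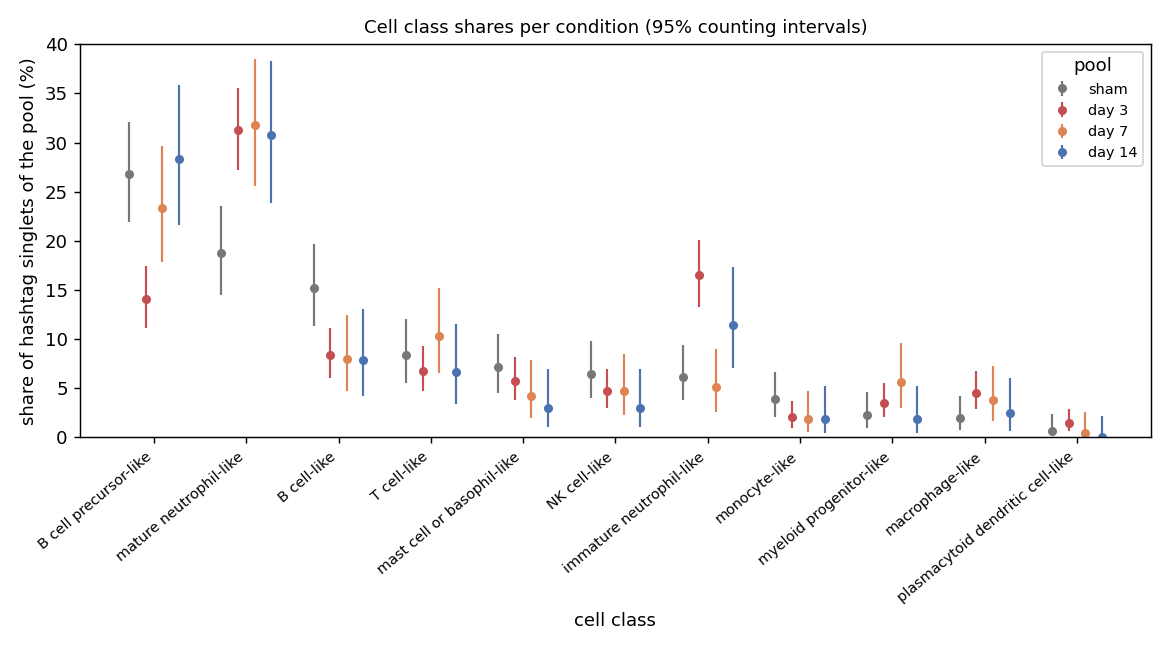
Share of each cell class among the CD45+ cells of a pool (%, vertical axis) for sham, day 3, day 7 and day 14, with 95% counting intervals as bars. Mature neutrophil-like cells were 18.7% of sham and 31.3% of day 3 cells, and B cell precursor-like cells 26.8% and 14.0%.

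Macrophage-like cells were 1.94% of sham (6 cells), 4.47% of day 3 (22 cells), 3.74% of day 7 (8 cells) and 2.41% of day 14 (4 cells), with a day 3 ratio of 2.31 (0.908 to 6.97). Monocyte-like cells were 3.87%, 2.03%, 1.87% and 1.81%, T cell-like cells 8.39%, 6.71%, 10.3% and 6.63%, and NK cell-like cells 6.45%, 4.67%, 4.67% and 3.01%. Mast cell or basophil-like cells were 7.10%, 5.69%, 4.21% and 3.01%, and myeloid progenitor-like cells 2.26%, 3.46%, 5.61% and 1.81%. Plasmacytoid dendritic cell-like cells numbered 2, 7, 1 and 0, where 0 of 166 cells leaves room for a share of up to 1.81% if counted as 3 cells (95% bound 2.198%). The classes typical of marrow stages (B cell precursor, immature neutrophil, myeloid progenitor, mast cell or basophil) together held 42.3%, 39.6%, 38.3% and 44.6% of the cells.

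Which genes differed in mature neutrophil-like cells on day 3? The class held 154 day 3 and 58 sham cells, spread over 4 clusters: one led by Il1b and Ccrl2 (46.1% of day 3 and 51.7% of sham cells), one by BC100530 and Mmp8 (18.2% and 25.9%), one by Ltf and Ly6g (21.4% and 17.2%) and one by Retnlg and Ccl6 (14.3% and 5.17%). Type I interferon response genes were higher on day 3, by a median log2 ratio of 1.16 (0.54 to 1.75), with 5 of 8 measured members at least 1.5-fold higher and 0 lower. Ifi27l2a, an interferon-induced mitochondrial protein gene, had 167 CPM against 46.7 in sham (ratio 3.57, 2.17 to 6.26), and Isg15, a ubiquitin-like protein, 144 against 52.2 (2.76, 1.71 to 4.70). Irf7, the transcription factor that amplifies interferon production, had a ratio of 3.56 (1.44 to 11.4). Inflammatory genes of the NF-kB list followed with a median log2 ratio of 0.44 (0.31 to 0.63) and 6 of 14 measured members higher. Among them, the prostaglandin synthase Ptgs2 had 331 CPM against 93.4 (3.55, 2.49 to 5.203), the cytokine Osm a ratio of 2.04 (1.53 to 2.77) and Il1b, which encodes interleukin 1 beta, 2897 CPM against 2197 (1.32, 1.22 to 1.43). The gene Ifi27l2a (ENSMUSG00000079017) lies on chromosome 12 from 103442167 to 103443680, and Ptgs2 (ENSMUSG00000032487) on chromosome 1 from 150100031 to 150108227.

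Chemokine genes in day 3 mature neutrophil-like cells had a median log2 ratio of 0.46 (0.29 to 0.58), but 68.8% of the Ccl3 UMIs and 47.2% of the Ccl4 UMIs came from 1 cell each, and the median was -0.06 without the top cell of each gene. Cxcl2, a neutrophil-attracting chemokine, had 1593 CPM against 1159 in sham (1.38, 1.24 to 1.53). Rgs1, a regulator of G protein signalling, had a ratio of 8.24 (2.17 to 69.9), while the stefin Stfa2 was at least 7.91-fold higher if 0 sham UMIs are counted as 3 (72 UMIs on day 3, 95% lower bound 6.27), with 84.7% of its UMIs in 1 cell. Lower on day 3 were the secreted phosphoprotein Spp1 (0.241, 0.126 to 0.452), the oxygen sensor Egln1 (0.256, 0.118 to 0.546), the xylosyltransferase Xylt1 (0.403, 0.267 to 0.611), Ube2a (0.383) and Nlrx1 (0.309). Immediate early genes had a median log2 ratio of 0.18 (-0.06 to 0.31), with 0 of 17 measured members at least 1.5-fold higher, and from 0.05 to 0.45 over 18 alternatives. That list also holds genes induced by tissue dissociation, and each pool was digested on its own.

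On day 7, did the same genes stay high in mature neutrophil-like cells? The interferon list had a median log2 ratio of -0.07 (-0.56 to 0.67) over 4 measured members in 68 cells, with Ifi27l2a at 2.08 times sham (1.17 to 3.89). NF-kB list genes had a median log2 ratio of -0.23 (-0.46 to -0.04; percentile 8.21), with 3 of 11 measured members at least 1.5-fold lower, among them Nfkbia (0.423, 0.314 to 0.567), while Il1b stood at 2116 CPM against 2197. Chemokine genes had a median of -0.46 (-0.75 to -0.18; percentile 1.58). Immediate early genes were lower, with a median log2 ratio of -0.77 (-1.07 to -0.69) and 15 of 17 measured members at least 1.5-fold lower. Egr1, an activity-induced transcription factor, had 139 CPM against 497 (0.280, 0.207 to 0.375), the AP-1 subunit Junb 1285 against 3147 (0.408, 0.369 to 0.451) and the stress-induced factor Atf3 a ratio of 0.306 (0.189 to 0.483). Cxcl2 had 325 CPM against 1159 (0.280, 0.231 to 0.339), and the chemokine-like receptor Ccrl2 168 against 571 (0.294, 0.223 to 0.384). Higher on day 7 were BC100530, a stefin family member (798 CPM against 214, ratio 3.73, 2.91 to 4.82), and the granule glycoprotein Olfm4 (1.76, 1.47 to 2.11). Glucocorticoid response genes had a median log2 ratio of -0.52 (-0.78 to -0.13), with 3 of 6 measured members lower and 1 higher, but -0.03 when members with at least 5 UMIs were counted. Egr1 (ENSMUSG00000038418) lies on chromosome 18 from 34859823 to 34864984, and Cxcl2 (ENSMUSG00000058427) on chromosome 5 from 90903871 to 90905938.

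Hypoxia and glycolysis genes of day 7 mature neutrophil-like cells had a median log2 ratio of 0.25 (0.05 to 0.39; 0.09 to 0.31 over 18 alternatives), with 1 of 10 measured members at least 1.5-fold higher, and the glucose transporter Slc2a3 had a ratio of 1.35 (1.09 to 1.67). Ublcp1, a proteasome phosphatase (3.49, 1.66 to 8.19), Ndufv3, a subunit of respiratory complex I (2.91, 1.55 to 5.86), and Tmem167 (2.90) were higher, and the ribosome assembly factor Nsa2 was lower (0.201, 0.0801 to 0.446). Of 3111 genes measured, the median log2 ratio was -0.03.

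Mature neutrophil-like cells of day 14 (51 cells) also had lower immediate early genes, with a median log2 ratio of -0.55 (-0.69 to -0.47) and 7 of 17 measured members at least 1.5-fold lower. Days 7 and 14 were divided by the same sham pool, so this is no independent repeat. A property of the sham pool, or of its digestion, cannot be told apart from a difference on these days. Atf3 had 25.3 CPM against 195 in sham (0.130, 0.0539 to 0.270), Egr1 a ratio of 0.318 (0.228 to 0.437), the AP-1 subunit Fosb 0.273 (0.116 to 0.573) and the cell cycle inhibitor Cdkn1a 0.144 (0.0370 to 0.406). Ccrl2 was at 0.420 times sham (0.319 to 0.549). Ptgs2 (2.61, 1.72 to 4.03), the lipid droplet protein Plin2 (2.38, 1.504 to 3.85), Ifi27l2a (2.64, 1.46 to 4.98) and the nucleoside kinase Dck (2.39, 1.46 to 4.03) were higher, as was BC100530 (2.596), although 53.4% of its day 14 UMIs and 41.6% of those of Ptgs2 came from 1 cell each. Glucocorticoid response genes had a median log2 ratio of -0.41 (-0.65 to -0.21), and the interferon list 0.24 (-0.25 to 0.99) over 4 measured members. The NF-kB list was at 0.07 (-0.07 to 0.28) and chemokines at 0.15 (-0.04 to 0.27).

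**Figure D2:**
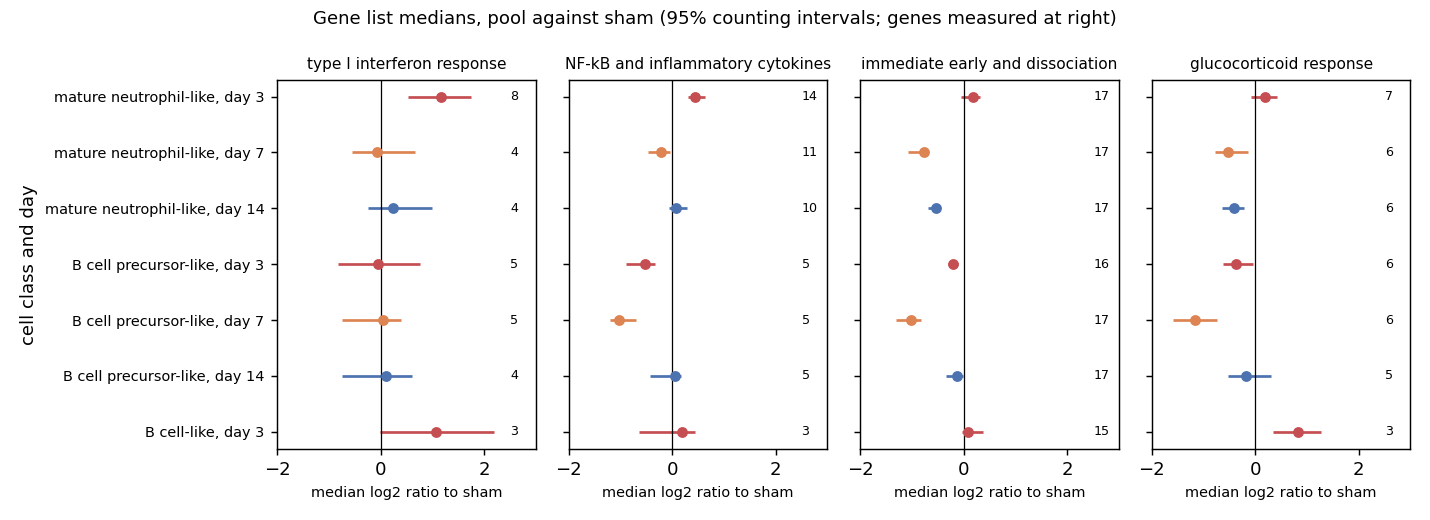
Median log2 ratio to sham (horizontal axis) of 4 gene lists for each cell class and day, with 95% counting intervals as bars and the number of genes measured at the right. The interferon list was at 1.16 in day 3 mature neutrophil-like cells, and immediate early genes were at -0.77 in these cells on day 7 and -1.02 in B cell precursor-like cells on day 7.

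How did B cell precursor-like cells of day 3 compare with sham? The class held 69 day 3 and 83 sham cells in 3 clusters: cycling cells (24.6% of day 3 and 26.5% of sham), cells with Vpreb1, Igll1 and Dntt (24.6% and 13.3%) and cells with Rag1 (50.7% and 60.2%). NF-kB list genes were lower, with a median log2 ratio of -0.53 (-0.89 to -0.34) and 2 of 5 measured members at least 1.5-fold lower, among them the adhesion molecule Icam1 (0.376, 0.217 to 0.628), and the median lay between -0.27 and -0.73 over 18 alternatives. The NF-kB inhibitor Nfkbia had 920 CPM against 1253 (0.734, 0.662 to 0.814). B cell activation genes had a median log2 ratio of -0.45 (-0.59 to -0.31), with 2 of 5 measured members lower, including the early activation antigen Cd69 (0.641, 0.559 to 0.734), but the median was between -0.13 and -0.25 under 6 alternatives. Immediate early genes had a median of -0.20 (-0.31 to -0.12), with Egr1 at 0.448 times sham (0.323 to 0.613), and from -0.66 to -0.045 over 18 alternatives. Higher on day 3 were the linker histone H1f0 (4.89, 2.24 to 12.2) and the calmodulin-binding protein Nrgn (3.104, 2.21 to 4.42). So were 3 genes of mitosis or nuclear import: the ubiquitin-conjugating enzyme Ube2c (676 CPM against 278, ratio 2.44, 2.06 to 2.89), Pimreg (3.44) and Kpna2 (2.86). The guanine exchange factor Rcc1 was lower (0.329, 0.167 to 0.610). Cox6a2 (0.0410), Tagap (0.0661), Ly6d (0.165) and AC140186.1 (0.254) were also lower, but 93.8%, 93.8%, 73.7% and 81.5% of their sham UMIs came from 1 cell. Tagap had at most 3 UMIs in either pool under 9 alternatives and AC140186.1 at most 2 under 5, with 13 UMIs against 1 under 3 more, while Ly6d was at 1.29 times sham (0.810 to 2.09) under 1. As reported, 84.6% of the 13 day 3 UMIs of AC140186.1 came from 1 cell.

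On day 7, 42.0% of the 50 B cell precursor-like cells lay in the cycling cluster (28.2 to 56.8) against 26.5% of sham (17.4 to 37.3), intervals that overlap. Cell cycle genes, which also define that cluster, had a median log2 ratio of 0.43 (0.38 to 0.54), with 7 of 19 measured members at least 1.5-fold higher, and -0.09 when the 3 clusters were weighted alike in both pools, which holds the cycling cluster at 1 weight by construction. The mitotic cyclin Ccnb1 had 251 CPM against 69.4 (3.62, 2.62 to 5.08) and Ube2c 725 against 278 (2.61, 2.21 to 3.101). Immediate early genes were lower, by a median log2 ratio of -1.02 (-1.30 to -0.82), with 13 of 17 measured members lower, and -0.54 with the clusters weighted alike. Fos had 31.6 CPM against 176 (0.179, 0.106 to 0.289), Egr1 37.9 against 190 (0.199, 0.124 to 0.309) and Junb 354 against 985 (0.359, 0.308 to 0.418). Antigen presentation genes of MHC class II had a median log2 ratio of -1.05 (-1.23 to -0.74) and 5 of 8 measured members lower, with the invariant chain Cd74 at 442 CPM against 1048 (0.422, 0.367 to 0.485). Ccnb1 (ENSMUSG00000041431) lies on chromosome 13 from 100778650 to 100786570.

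Several more gene lists were lower in day 7 B cell precursor-like cells, but the glucocorticoid, NF-kB, B cell activation and T cell activation lists share genes with each other or with the immediate early list (Dusp1, Nfkbia, Egr1 and Cd69) and are not separate results. Glucocorticoid response genes had a median log2 ratio of -1.16 (-1.59 to -0.75), with 5 of 6 measured members lower, among them the leucine zipper gene Tsc22d3 (0.357, 0.265 to 0.476), while the kinase Sgk1 was higher (1.68, 1.09 to 2.604). NF-kB list genes had a median of -1.02 (-1.20 to -0.69) and 4 of 5 measured members lower, with Nfkbia at 0.493 times sham (0.437 to 0.556). B cell activation genes had a median of -0.90 (-1.06 to -0.71), with 3 of 5 measured members lower, but -0.18 when members with at least 5 UMIs were counted. The 3 measured members of the T cell activation list had a median of -0.95, among them Cd69 (0.536, 0.462 to 0.621). MHC class I genes had a median of -0.37 (-0.43 to 0.04), with 0.05 when clusters were weighted alike. H1f0 (5.55) and Nrgn (3.101) were higher, as on day 3 against the same sham pool, in which H1f0 had 8 UMIs. The immunoglobulin constant gene Ighg2b was higher too (9.68, 4.15 to 27.6). Lower were Cox6a2 (0.0177), AC140186.1 (0.0422), the transcription factor Runx2 (0.0380) and the adaptor Tyrobp (0.156), and Tagap had 0 UMIs against 48, but 50.5% to 93.8% of the sham UMIs of these 5 genes came from 1 cell each. Tagap, Runx2 and AC140186.1 had 3 UMIs or fewer in both pools under 8, 7 and 7 alternatives, which give no direction.

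In day 14 B cell precursor-like cells (47 cells), the cycling cluster held 23.4% and cell cycle genes had a median log2 ratio of 0.09 (-0.11 to 0.15). Genes of the B cell precursor list had a median of 0.32 (-0.06 to 0.42; 0.04 to 0.46 over 17 alternatives), with 2 of 11 measured members at least 1.5-fold higher: Igll1 (658 CPM against 376, ratio 1.75, 1.47 to 2.08) and Vpreb1 (1206 against 801, ratio 1.51, 1.33 to 1.70). Ube2c was higher (2.42, 2.003 to 2.92), as were the apoptosis regulator Hax1 (3.71), Taf13 (3.16), Impdh1 (2.55) and Ncf4 (2.52). Monocyte entry genes had a median of -1.15 (-1.58 to -0.66), with 4 of 6 measured members lower, among them Plac8 (0.453, 0.356 to 0.572), and between -0.35 and -0.65 under 8 alternatives. Immediate early genes had a median of -0.12 (-0.33 to -0.01), although Fos stood at 0.204 times sham (0.109 to 0.355) and Fosb at 0.265 (0.116 to 0.535). At the higher of the 2 alternative hashtag quantiles Fos was 1.10 times sham. Cox6a2 (0.0862), Fcer1g (0.0545), Tagap (0.116) and AC140186.1 (0 UMIs against 54) were lower, but 67.6% to 93.8% of their sham UMIs came from 1 cell. Tagap, Fcer1g and AC140186.1 had 3 UMIs or fewer in both pools under 8, 7 and 7 alternatives, which give no direction, and Cox6a2 was at 1.23 times sham (0.316 to 4.25) without the top cell of each gene.

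In B cell-like cells of day 3 (41 cells against 47), the median log2 ratio of all 3415 measured genes was 0.37, and 1 sham cell held 53.0% of the sham UMIs of Igkc, the kappa light chain constant gene, at 160880 CPM in the class. Size factors brought this median to 0.00, and the values for genes that were higher are given after that scaling. Ifi27l2a was then 4.29 times sham, Plac8 2.94, the small GTPase Rasd1 3.81, the lambda constant gene Iglc1 2.07 and the GTPase Rrad 3.54. Before that scaling, with random lists at a median of 0.39, interferon genes had a median log2 ratio of 1.07 (-0.02 to 2.19, 3 measured members; percentile 98.4). Immediate early genes had 0.08 (-0.03 to 0.38; 15 measured members), below those random lists (percentile 0.07), and -0.29 after that scaling. Jchain, the chain that joins secreted antibodies, had 2 UMIs against 8426, and the IgA constant gene Igha 175 CPM against 44772. Igkc (0.0752), Ly6c2 (0.0266) and the protease inhibitor Slpi (0.0328) were lower too, but 51.1% to 64.0% of the sham UMIs of these 5 genes came from 1 cell each. Under 3 alternatives Jchain and Ly6c2 had 2 UMIs or fewer in both pools and Igha had 38 UMIs against 2. As reported, 94.7% of the 38 day 3 UMIs of Igha came from 1 cell. The lower values of these 3 genes thus depended on which sham cells were placed in the class. Jchain is a plasma cell marker, but whether those sham cells were plasma cells was not tested.

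Which cells held the inflammatory transcripts? Over the 4 pools together, mature neutrophil-like cells held 89.5% of the 6469 Il1b UMIs, 78.7% of Ptgs2, 80.7% of the interleukin 1 antagonist Il1rn and 86.7% of Ccl6. Macrophage-like cells held 88.2% of the monocyte attractant Ccl2, 97.51% of Ccl12, 96.1% of Ccl7 and 81.6% of Cxcl16. For Cxcl2, 61.0% of UMIs lay in mature neutrophil-like cells, but its level was higher in macrophage-like cells (1582 CPM against 1216 CPM). NK cell-like cells held 74.9% of Ccl5, and mast cell or basophil-like cells 96.1% of the 179 UMIs of Il6.

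Hashtag recovery differed between classes. In a clustering of all barcodes that passed the filter, 88.8% of mature neutrophil-like barcodes (85.2 to 91.8) carried a single hashtag, 89.4% of B cell precursor-like (85.2 to 92.7), 94.96% of B cell-like, 91.9% of T cell-like, 82.2% of immature neutrophil-like (75.0 to 88.0) and 81.6% of macrophage-like barcodes. Their leading hashtag had a median of 201 UMIs in mature and 186 in immature neutrophil-like barcodes, against 532 in T cell-like barcodes.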

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

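Thinning cells to 1 depth was among the first alternatives, but its bound and the other tests in this part were chosen only after the result was seen. A group of barcodes that enters no condition held a signal of its own. In 42 barcodes without a hashtag, the transthyretin gene Ttr had 197 UMIs per barcode and 31.7% of 26014 UMIs, with the phospholipase Enpp2 at 7.24 UMIs per barcode. All CD45+ singlets together held 4 Ttr UMIs in 1182 cells. The 42 barcodes also held 1500015O10Rik (106 UMIs against 0 in all singlets), Sostdc1 (39 against 0), Folr1 (26 against 1) and Igfbp2 (26 against 0). The inner ear gene Coch and the fibroblast gene Col1a1 had 0 UMIs in them (2 and 21 in all singlets). The gene for CD45, Ptprc, had 0 UMIs in the 42 barcodes where 12.9 were expected at the level of the singlets.

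For the Ttr barcodes, free RNA shared by all droplets was argued against, since singlets held 0.0017% of their Ttr UMIs per barcode. Reads of another library were argued against too, since the background neutrophil genes S100a8 and S100a9 were present at 0.458 times their level in T cell-like barcodes (0.388 to 0.538). Hashtag UMIs per barcode were 0.234 times those of the other hashtags in singlets (0.154 to 0.340), with a median of 0. Any value below 1 would have passed for cells of another tissue that the antibodies did not stain. It would also hold for reads of another library, so the hashtags do not separate these explanations. Why the value lay below the background of singlets was not tested. A CD45 gate would remove unstained cells of another tissue, and how such cells could have passed it was not tested. Which tissue the barcodes came from was not tested either.

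The NF-kB list stood out by medians of opposite sign in 2 cell classes on day 3. The median log2 ratio was 0.44 over 14 measured members in mature neutrophil-like cells. In B cell precursor-like cells it was -0.53 over 5 measured members. The member sets differ, so the medians do not show the same genes moving in opposite directions. This difference was not tested, since each condition is 1 pool.

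Mature neutrophil-like cells had a higher share on day 3 than in sham (31.3% against 18.7%) and B cell precursor-like cells a lower one (14.0% against 26.8%; ratio 0.524, or 0.754 without neutrophil classes in the denominator, where its interval of 0.540 to 1.05 includes 1). A different amount of bone marrow would change immature neutrophil-like and B cell precursor-like shares alike, yet their changes differed by a factor of 5.13 (2.74 to 9.81). More residual blood would add lymphoid cells, but B, T and NK cell-like cells per other cell outside the neutrophil classes were at 0.913 times sham (0.624 to 1.34), which leaves it open. Giving day 3 all 30 B cell precursor-like barcodes not called singlets would bring its share to 19.2%, below the lower bound of sham (21.9%). Giving sham all 43 such mature neutrophil-like barcodes would bring its share to 29.2%, inside the day 3 interval that starts at 27.2%. All 43 carried more than 1 hashtag and 0 carried none, so giving every one to sham is an extreme case. The margin rule called 107 hashtag doublets of all classes singlets. Over 12 alternatives, the hashtag rules among them, the day 3 share ratio of mature neutrophil-like cells stayed between 1.46 and 1.75 (reported 1.67). This argues against missed calls as the whole cause, as far as barcodes were re-called. How many of the 43 were among them was not tested. For the neutrophil part, missed calls of the remaining barcodes stay open. So do residual blood, noise itself and any difference between pools, which 1 pool per condition cannot tell apart.

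Type I interferon genes were higher in day 3 mature neutrophil-like cells (median log2 ratio 1.16), above 0.46, which is the median of matched random lists plus 2 SD. Without the top cell of each gene in both pools the median was 1.32. For Ifi27l2a that cell held a larger part of the sham UMIs than of the day 3 UMIs, so leaving it out can raise the ratio. Whether a few day 3 cells caused the difference therefore cannot be decided by it. With the 4 clusters weighted alike the median was 1.52, and with cells thinned to 1 depth 1.19. The mix of clusters and depth were thus each argued against as the whole cause. A response to noise is a candidate explanation, and so is any handling or infection that touched the day 3 pool alone. These cannot be told apart with 1 pool per day.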

How the results depend on the processing

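Values without the top cell of each gene and with clusters weighted alike come from alternatives chosen only after the results were seen. No paired analysis was possible because each condition is 1 pool. Over all alternatives, 367 of 371 share ratios stayed inside the counting interval of the reported value, 4 moved beyond it and 0 reversed a ratio whose interval excluded 1. Of the 371, 18 lay on the other side of 1 from the reported ratio, all where its interval included 1. Shares themselves stayed inside in 440 of 512 values, and 72 moved. Of 382 list medians, 306 stayed inside, 65 moved and 11 reversed, and of 1039 ratios of named genes 869 stayed inside, 158 moved and 12 reversed. Another 64 gene values were left out because both pools held 3 UMIs or fewer there. In the 12 alternatives that apply, the share ratio of mature neutrophil-like cells lay between 1.46 and 1.75 on day 3, 1.58 and 1.88 on day 7, and 1.48 and 1.76 on day 14. The interferon list of day 3 mature neutrophil-like cells lay between 0.86 and 1.69 over 18 alternatives. In the same cells, lists lay between 0.27 and 0.70 (NF-kB, day 3), 0.05 and 0.45 (immediate early, day 3), -1.10 and -0.59 (immediate early, day 7), -0.74 and -0.37 (immediate early, day 14) and 0.09 and 0.31 (hypoxia, day 7). In B cell precursor-like cells of day 7 they lay between -1.29 and -0.70 (MHC class II), -1.27 and -0.80 (glucocorticoid), -1.15 and -0.68 (NF-kB), -1.12 and -0.54 (immediate early) and -1.05 and -0.63 (T cell activation). Precursor genes of day 14 lay between 0.04 and 0.46. At most 5% mitochondrial UMIs kept 926 cells and 4 of the 7 comparisons, while the 0.95 hashtag quantile (1004 cells) and Leiden resolution 0.5 kept 6 each. Counting genes of at least 100 UMIs, or shares without erythroid, platelet and non-immune clusters, changes no value by construction.

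Shares and single genes are given as ratios to sham, and lists as median log2 ratios. The cause was not tested where no cause is given. Without neutrophil classes in the denominator, the day 3 share ratio of B cell precursor-like cells was 0.754 (0.540 to 1.05), so its interval no longer excluded 1, nor did those of B cell-like cells. With at most 5% mitochondrial UMIs, the share ratio of B cell-like cells was 0.197 on day 14 (0.005 to 1.42, which now includes 1) and that of T cell-like cells 0.418 on day 3 (0.187 to 0.914, which now excludes 1). The same filter put day 3 B cell precursor-like cells at 1.29 for Ly6d (0.810 to 2.09) and -0.66 for immediate early genes.

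Clustering choices moved several values. At Leiden resolution 2, the day 3 share ratio of mast cell or basophil-like cells was 0.378 (0.059 to 1.94). B cell precursor-like cells then had AC140186.1 at 12.6 on day 3 (1.89 to 536; 13 UMIs against 1) and Cox6a2 at 1.27 on day 14 (0.365 to 4.19). Their lists were at -0.46 (MHC class I) and 0.55 (cell cycle) on day 7, and at -0.64 (monocyte entry) on day 14. At Leiden resolution 0.5, the same class had AC140186.1 at 14.9 on day 3 (2.24 to 634). Lists there were at -0.27 (NF-kB), -0.045 (immediate early) and -0.15 (B cell activation) on day 3, 0.84 (cell cycle) on day 7 and -0.35 (monocyte entry) on day 14.

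With singlets alone clustered, the lists of B cell precursor-like cells were at -0.22 (B cell activation) on day 3, 0.80 (cell cycle) on day 7, and -0.45 (monocyte entry) and 0.46 (precursor genes) on day 14. Day 3 B cell-like cells had Igha at 18.1 (4.67 to 155; 38 UMIs against 2) and immediate early genes at -0.22. Without the Scrublet doublets, AC140186.1 was at 12.7 on day 3 in B cell precursor-like cells (1.91 to 540). Cell cycle genes were at 0.54 on day 7, and on day 14 Cox6a2 was at 1.28 (0.367 to 4.22) and monocyte entry at -0.65. In B cell-like cells of day 3, Igha was at 19.1 (4.95 to 164) and immediate early genes at -0.21. With at least 500 genes per cell, the lists of B cell precursor-like cells were at -0.25 (B cell activation) on day 3, 0.78 (cell cycle) on day 7, and -0.47 (monocyte entry) and 0.46 (precursor genes) on day 14. That filter put day 3 B cell-like cells at 19.5 for Igha (5.03 to 167) and -0.14 for immediate early genes.

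Hashtag calls moved others. At the lower quantile (0.95), the lists of B cell precursor-like cells were at -0.094 (immediate early) and -0.13 (B cell activation) on day 3, and at -0.52 (B cell activation), -1.29 (MHC class II) and -0.63 (T cell activation) on day 7. Monocyte entry was at -0.45 on day 14. Mature neutrophil-like cells had NF-kB genes at 0.69 and chemokines at 0.61 on day 3, and immediate early genes at -0.61 and -0.45 on days 7 and 14. At the higher quantile, B cell precursor-like cells were at -0.32 (NF-kB) and -0.13 (B cell activation) on day 3, and at -0.70 (MHC class II), -0.79 (immediate early) and 0.55 (cell cycle) on day 7. Their day 14 values were 1.11 for Fcer1g (0.732 to 1.66), 1.10 for Fos (0.899 to 1.35) and -0.61 for monocyte entry. Immediate early genes of mature neutrophil-like cells were at 0.36, -0.68 and -0.39 on days 3, 7 and 14. The margin rule put the lists of B cell precursor-like cells at -0.32 (NF-kB) and -0.19 (B cell activation) on day 3, 0.58 (cell cycle) on day 7 and -0.49 (monocyte entry) on day 14. For mature neutrophil-like cells the rule gave 0.40, -0.63 and -0.37 for immediate early genes.

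Normalization and depth mattered for a few lists. As a mean over cells, day 7 B cell precursor-like cells were at -0.68 (NF-kB), -0.58 (immediate early) and 0.61 (cell cycle). Mature neutrophil-like cells were at 0.17 for chemokines on day 3 and -0.74 for immediate early genes on day 14. In day 3 B cell-like cells, immediate early genes were at -0.30 as a mean over cells, -0.29 with size factors and -0.11 with cells thinned to 1 depth. Thinning put day 7 B cell precursor-like cells at -0.70 (MHC class II), 0.058 (MHC class I) and 0.56 (cell cycle). It put mature neutrophil-like cells at 0.73 (chemokines) on day 3, -0.82 (glucocorticoid) on day 7, and 0.36, -1.10 and -0.43 (immediate early) on days 3, 7 and 14. Counting members of at least 5 UMIs gave -0.18 for B cell activation in day 7 B cell precursor-like cells, and -0.077 (chemokines, day 3) and -0.029 (glucocorticoid, day 7) in mature neutrophil-like cells.

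Leaving out the top cell of each gene gave B cell precursor-like cells Cox6a2 at 1.23 on day 14 (0.316 to 4.25). It gave day 3 mature neutrophil-like cells 0.27 for NF-kB genes and -0.062 for chemokines. Chemokines also reversed with members of at least 5 UMIs, and the lower Cox6a2 of day 14 rests on 1 sham cell. Weighting clusters alike put day 7 B cell precursor-like cells at 0.054 (MHC class I), -0.54 (immediate early), -0.088 (cell cycle) and -0.60 (B cell activation). The cycling cluster is defined by cell cycle genes, so this weighting removes a cell cycle difference by construction. It put mature neutrophil-like cells at 0.70 (NF-kB) on day 3, and at 0.45 and -0.59 (immediate early) on days 3 and 7.

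Depth limits the comparisons. Macrophage-like, monocyte-like and plasmacytoid dendritic cell-like cells were too few in sham for a comparison of genes by the 30-cell rule. Lists for erythroid, platelet and non-immune cells never reached 3 measured members in the classes compared.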

Other observations

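The comparisons in this part were chosen only after the data were seen. Macrophage-like cells were too few for the 30-cell rule, but they held the highest summed level of interferon response genes of the 11 classes on day 3. Most of that sum was Ifi27l2a. The 20 genes of that list made up 649 UMIs per 1000000 in sham (434 to 931; 6 cells), 8840 on day 3 (8555 to 9131; 22 cells), 3251 on day 7 (2887 to 3648; 8 cells) and 864 on day 14 (528 to 1335; 4 cells). Ifi27l2a alone was at 246 CPM in sham (123 to 440), 5646 on day 3 (5420 to 5880) and 1519 on day 7 (1273 to 1797), and was detected in 22 of 22 day 3 cells. Irf7 had 0 UMIs in sham and 561 CPM on day 3, the antiviral membrane protein Bst2 112 and 643 CPM, and Isg15 44.7 and 256 CPM. Over all pools, Bst2 was higher in plasmacytoid dendritic cell-like cells (3666 CPM) than in macrophage-like cells (542 CPM). Macrophage-like cells had a median of 4690 UMIs in sham and 19380.5 on day 3. The cell with the most list UMIs held 13.8% of them on day 3.

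In other classes the same list was at 1162, 2304, 1937 and 526 UMIs per 1000000 in T cell-like cells (sham, day 3, day 7, day 14), although 63.0% of the sham UMIs came from 1 cell, and at 988, 1910, 990 and 594 in monocyte-like cells. T cell-like cells (33 on day 3, 26 in sham) had 9 of 10 measured interferon genes at least 1.5-fold higher on day 3, with a median log2 ratio of 2.503, in which 3 members without sham UMIs stand at their bound. Isg15 had a ratio of 13.8 (3.60 to 118). Immature neutrophil-like cells (81 on day 3, 19 in sham) had 13 of 19 cell cycle genes higher and 3 lower on day 3, with Ube2c at 17.5 times sham (5.92 to 85.7) and Mki67, a proliferation marker, at 7.05 (3.52 to 16.5). In sham, 1 cell held 87.5% of the 8 Mki67 UMIs. On day 14 (19 cells), 14 of 19 cell cycle genes were higher and 4 lower, with a median log2 ratio of 2.12 and Ube2c at 54.8 times sham (18.5 to 268; 3 sham UMIs).

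The share of all classes typical of marrow stages was 0.938 times sham on day 3 (0.748 to 1.18), 0.907 on day 7 (0.679 to 1.204) and 1.05 on day 14 (0.782 to 1.41). Of all 152 barcodes without a hashtag, 139 held at least 10 Ttr UMIs, and Ttr made up 29.5% of their UMIs.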
